A study of Homo sapiens with 4 samples.

How the data were processed

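RNA-seq of HCT116 cells was deposited as 1 table per library, with 4 libraries in 2 groups, DMSO and HJ-23. Each table gives an Ensembl gene identifier and a whole-number count for 20263 genes, and the authors deposited these counts without normalization, as the values show; they were whole numbers, so the rounding foreseen for estimated counts was not needed. The submitters' processing notes name FastQC, Trimmomatic, HISAT2, bedtools and RSEM, without versions or roles; the counter's settings, the strand setting and the genome build are not given in the sources used here. Among genes with 1 to 8 counts, 69.6% to 72.3% of the values per library were even, against 49.7% to 50.8% of values above 50, so both mates of a pair appear to have been counted for most fragments, and the deposited counts are then closer to reads than to fragments. PCR copies cannot be told from separate molecules, and the floor used for counts of 0 (6 counts per library, 3 fragments with both mates counted) covers counting error only.

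Groups and replicate numbers were taken from the sample titles. The treatment field of the treated samples names HJ-25 where the titles and the design text name HJ-23; the name in the titles is used. The deposited tables carry the letter D for the libraries titled DMSO and C for those titled HJ-23; what the letters stand for is not given in the sources used here, and the direction of every fold change rests on the titles. Gene symbols came from a gene name table for 20148 identifiers and from GENCODE 29 alone for 76, and 39 were in neither. Transcript GC content, length and the readthrough tag came from GENCODE 29; a gene was taken as a readthrough gene where every transcript has that tag. Since overlapping genes and close paralogs can share reads, their values are uncertain.

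Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM scaling (factors from 0.983 to 1.03), filterByExpr with the group (14062 genes kept), robust dispersions, and the quasi-likelihood F-test in its legacy form, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The model had 2 residual degrees of freedom and 3.98 prior degrees of freedom, and the biological coefficient of variation was 19.6%. Fold changes are HJ-23 over DMSO on the log2 scale, computed here from the deposited counts; the standard error is the log2 fold change divided by the square root of F. Levels are in CPM, the count divided by the TMM-scaled library size, as mean ± SD over the 2 libraries. As a check for a library deposited again under another name, chi-square over its degrees of freedom was 37.6 for the DMSO pair and 73.6 for the HJ-23 pair, against 59.5 and 69.2 between HJ-23 replicate 1 and DMSO replicates 1 and 2, and 91.4 and 144.3 between HJ-23 replicate 2 and these. Counting both mates raises this ratio by itself, so these values are read only against a repeated deposit of the same counts.

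Before the data were examined, 38 gene lists with 950 symbols were fixed (7 symbols had no match), and the 33 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with the estimated correlation and fry beside it. Counts of passing members are given adjusted over the list alone and over all genes tested. The named genes were also set by a rule fixed then. It took up to 6 genes with the largest increase and 6 with the largest decrease past the threshold, with a mean of at least 10 CPM, a protein-coding symbol and groups that do not overlap. It added up to 2 passing members, with a mean of at least 5 CPM, of each of the 8 response lists with the smallest camera p and of any other list described, and CDKN1A, HMOX1, DDIT3, MYC, MKI67, ACTB and GAPDH. The rule gave 15 genes, and other genes are named as chosen after their values were seen.

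The fits were tested on simulated data for HJ-23 against DMSO, made from the real means and library sizes, with 5 simulations of 100 changed genes at each of 2 sizes. Without a library trend (13937 genes tested) edgeR recovered 43.0% of genes changed by 1 on the log2 scale and 94.4% of those changed by 2, and 12.4% of its calls were false. DESeq2 (14062 genes tested) recovered 62.0% and 94.4%, with 21.9% of calls false. Without a library trend edgeR made 157.8 calls on average, against 12 in the real data. The adjusted threshold is stricter when fewer genes pass, so these recovery rates do not carry over to the real data. With the libraries' own GC and length trend added within each group, its group means removed, edgeR recovered 40.4% and 94.4%, with 11.5% of calls false. With the GC and length correction edgeR recovered 58.2% and 94.0% there, with 14.1% of calls false. Those simulations used the dispersions of the GC and length corrected fit. They do not cover a trend between the groups, which the data also had (Spearman 0.38 with GC content). Camera called the moved list in 5 of 5 simulations, and 0.4% of 250 unchanged lists had an unadjusted p below 0.05. Genes were drawn independently in these simulations, so the 0.4% does not hold for lists whose genes are correlated. The tubulin list, for example, had an estimated correlation of 0.73 in the real data.

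The analysis was also repeated with DESeq2 size factors, no TMM scaling, no filter, a filter at 10 CPM, the replicate number as a block, leaving out each library, DESeq2 1.42.0 with its own filter on all genes with a count (so that both test and filter differ), limma-voom and the newer edgeR quasi-likelihood fit. Chosen after seeing the data were per-library loess corrections (span 0.4) for GC content and for GC content and length, a crossed block, both blocks with the correction, and a fit without readthrough genes. Figures were drawn with matplotlib from the computed tables. Genome coordinates are left out because the build is not stated, and the values of 1 called readthrough gene are not reported here.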

Results

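RNA was sequenced from HCT116 cells, an established human colorectal carcinoma line, after 24 hours with 30 µM HJ-23 or with 0.1% DMSO, the solvent control. HJ-23 is called a piperine derivative by the submitters, and no structure is given in the sources used here. Each group had 2 libraries. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Total counts were 31120459 and 29769568 in DMSO replicates 1 and 2, and 34406649 and 34831207 in HJ-23 replicates 1 and 2. Between 15533 and 15754 of the 20263 genes listed had a count in each library. The single comparison the design gives asks how transcript levels in HJ-23-treated cells differed from those in solvent-treated cells. The genome build of the authors' counting is not given in the sources used here, so genes are named by symbol and identifier without coordinates.

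Treated cells had more mRNA for BBC3, ATF5, GDF15, TMEM250 and ZFP90 and less for BNIP3L, GNA12 and ACER3. BBC3 (ENSG00000105327), the pro-apoptotic BH3-only protein PUMA, rose from 21.7 ± 1.91 to 135.1 ± 39.7 CPM (library-scaled counts, mean ± SD, n = 2 per group), a log2 fold change of 2.64 (SE 0.24, adjusted p = 0.0451, edgeR). GDF15 (ENSG00000130513), a secreted stress-induced cytokine, rose from 155.3 ± 8.74 to 721.1 ± 149 CPM (log2 fold change 2.22, SE 0.19, adjusted p = 0.0382, edgeR). ATF5 (ENSG00000169136), a basic leucine zipper transcription factor of the stress response, rose from 3.15 ± 0.15 to 17.8 ± 1.75 CPM (2.498, SE 0.20, adjusted p = 0.0304, edgeR). TMEM250 (ENSG00000238227), a predicted membrane protein, rose from 8.07 ± 0.15 to 50.9 ± 9.73 CPM (2.66, SE 0.21), and ZFP90 (ENSG00000184939), a zinc finger protein, from 3.59 ± 0.34 to 17.99 ± 1.63 CPM (2.33, SE 0.20).

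BNIP3L (ENSG00000104765), a mitophagy receptor induced by hypoxia, fell from 166.6 ± 15.8 to 42.3 ± 2.49 CPM (log2 fold change -1.98, SE 0.15, adjusted p = 0.0304, edgeR). ACER3 (ENSG00000078124), an alkaline ceramidase, fell from 55.4 ± 5.59 to 10.8 ± 2.38 CPM (-2.36, SE 0.22, adjusted p = 0.0474, edgeR). GNA12 (ENSG00000146535), a G protein alpha subunit, fell from 60.8 ± 1.498 to 17.2 ± 1.27 CPM (-1.82, SE 0.16, adjusted p = 0.0447, edgeR).

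**Figure D1:**
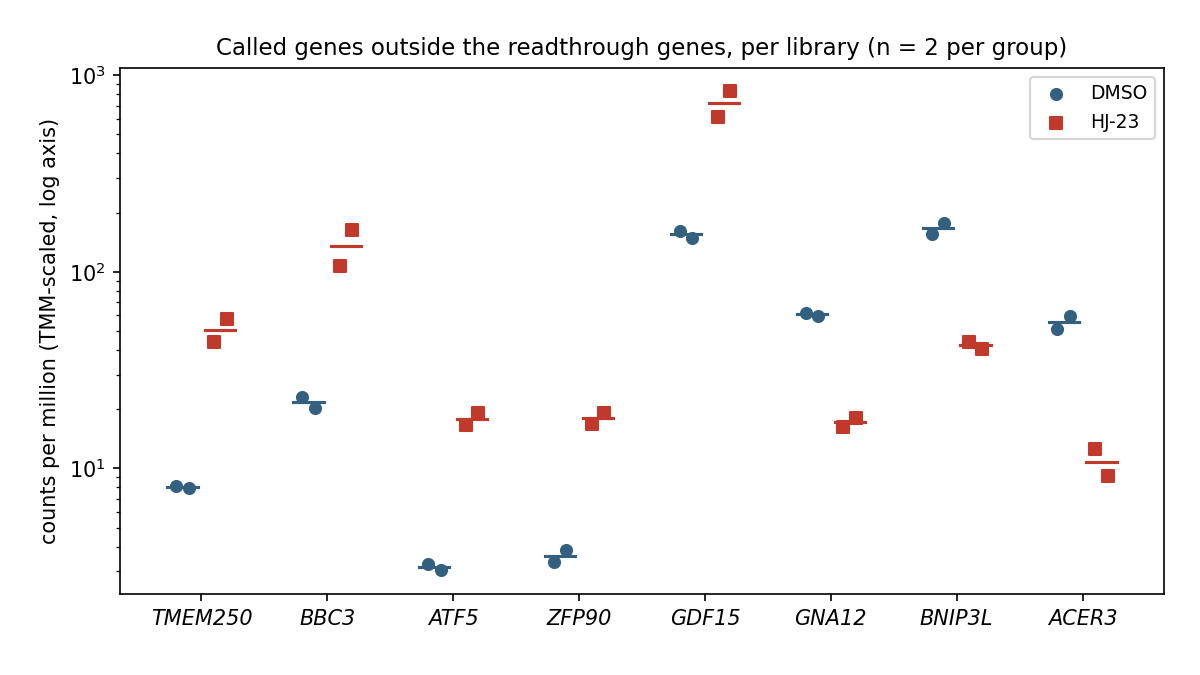
TMM-scaled CPM (log axis) of the 8 called genes that are not readthrough genes, with 1 point per library, circles for DMSO, squares for HJ-23 and a short line at each group mean (n = 2). For every gene shown, both HJ-23 libraries lie on the same side of both DMSO libraries, as for BBC3 with means of 21.7 and 135.1 CPM.

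The other 4 genes past the threshold are annotated as readthrough genes, whose transcripts join exons of neighbouring genes and share reads with them, so their values are uncertain. CORO7-PAM16 was at 0.22 ± 0.08 CPM in DMSO and 11.7 ± 1.15 CPM in HJ-23 (log2 fold change 5.74, SE 0.32, adjusted p = 0.0255, edgeR). ENSG00000282034 was higher in HJ-23 with a log2 fold change of 2.95 (SE 0.22). ENSG00000256349 had 199 and 215 counts in the DMSO libraries and 0 in both HJ-23 libraries, at least 40.0-fold lower with 6 counts per library (3 fragments with both mates counted) as the floor. These genes were chosen after their values were seen.

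Over the 14062 genes tested with edgeR's quasi-likelihood test, 8 were higher and 4 lower in HJ-23 at an adjusted p below 0.05, and all 12 differed at least 2-fold. At an unadjusted p below 0.05 there were 952 higher and 738 lower genes, 12.02% of those tested. Both HJ-23 libraries lay above both DMSO libraries for 3489 genes and below them for 2980, together 46.0% of genes. Chance gives 33.3% for a gene whose 4 libraries are exchangeable. Genes move together within a library, along GC content for example, so the share can exceed 33.3% without an effect of treatment. Other splits of the 4 libraries were not examined. DESeq2, which used its own filter on the 16717 genes with a count in any library, called 161 genes higher and 150 lower, among them all 12. In the simulations without a library trend 21.9% of DESeq2's calls were false, against 12.4% of edgeR's, so a gene passing with DESeq2 alone is less certain. With only 1 HJ-23 library in the fit edgeR called 0 genes, whichever was left out (3501 at an unadjusted p below 0.05 without HJ-23 replicate 1 and 1377 without replicate 2). It called 273 without DMSO replicate 1 and 157 without DMSO replicate 2.

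Of the 38 gene lists fixed in advance, 33 had at least 5 tested members, and camera with a preset correlation found 9 higher and 9 lower in HJ-23. With an estimated correlation 0 of the 18 remained called, and the smallest adjusted p was 0.194. That form of the test rests on the 2 residual degrees of freedom, so it has little power with 4 libraries. The hypoxia list, with an estimated correlation of -0.027, below the preset 0.01, went from a camera p of 4.37e-21 to 0.00908. Losing a call this way is therefore not by itself a sign of correlated genes. Across the 18 called lists the estimated correlation ran from -0.037 (ferroptosis) to 0.73 (tubulins). It was 0.54 for the mitochondrial list, 0.48 for glycolysis, 0.24 for G2/M and 0.14 for the integrated stress response. Where genes are correlated above the preset 0.01, the camera p-values at the preset are too small. Fry called 4, the hypoxia, NF-kB, NRF2 and interferon lists, with adjusted p-values of 0.0134, 0.0407, 0.0407 and 0.0470. Genes named for a list that are neither among the 8 above nor fixed in advance were chosen after their values were seen.

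Targets of ATF4 and the integrated stress response, the program that follows amino acid shortage and other stresses, were higher in HJ-23. Of 31 tested members, 29 had a positive log2 fold change and the median was 0.85. Adjusted over the list alone, 23 rose and 0 fell; over all genes tested, 1 rose, GDF15. The camera adjusted p was 3.21e-32 (adjusted p = 0.194 with an estimated correlation). ASNS, which makes asparagine, was at 188.2 ± 2.51 CPM in DMSO and 444.9 ± 2.54 in HJ-23, and PPP1R15A, which directs dephosphorylation of eIF2-alpha, at 137.9 ± 3.66 and 364.8 ± 44.9. Adjusted over the list alone both rose (edgeR adjusted p = 8.57e-04), and over all genes neither passed (edgeR adjusted p = 0.0650 and 0.0695), though both did with DESeq2 and with the GC and length correction. The serine synthesis enzyme PSAT1 and the amino acid transporter SLC7A5 rose adjusted over the list alone, with log2 fold changes of 1.18 and 1.37. DDIT3, the transcription factor CHOP, fixed in advance, was at 74.8 ± 16.4 and 145.0 ± 62.4 CPM and did not pass (log2 fold change 0.96, SE 0.32, adjusted p = 0.362, edgeR). ASNS, PPP1R15A, PSAT1 and SLC7A5 were chosen after their values were seen. The list of ATF6 and XBP1 targets, the other arms of the endoplasmic reticulum stress response, had a median of 0.041 over 23 members and was not called (adjusted p = 0.495).

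**Figure D2:**
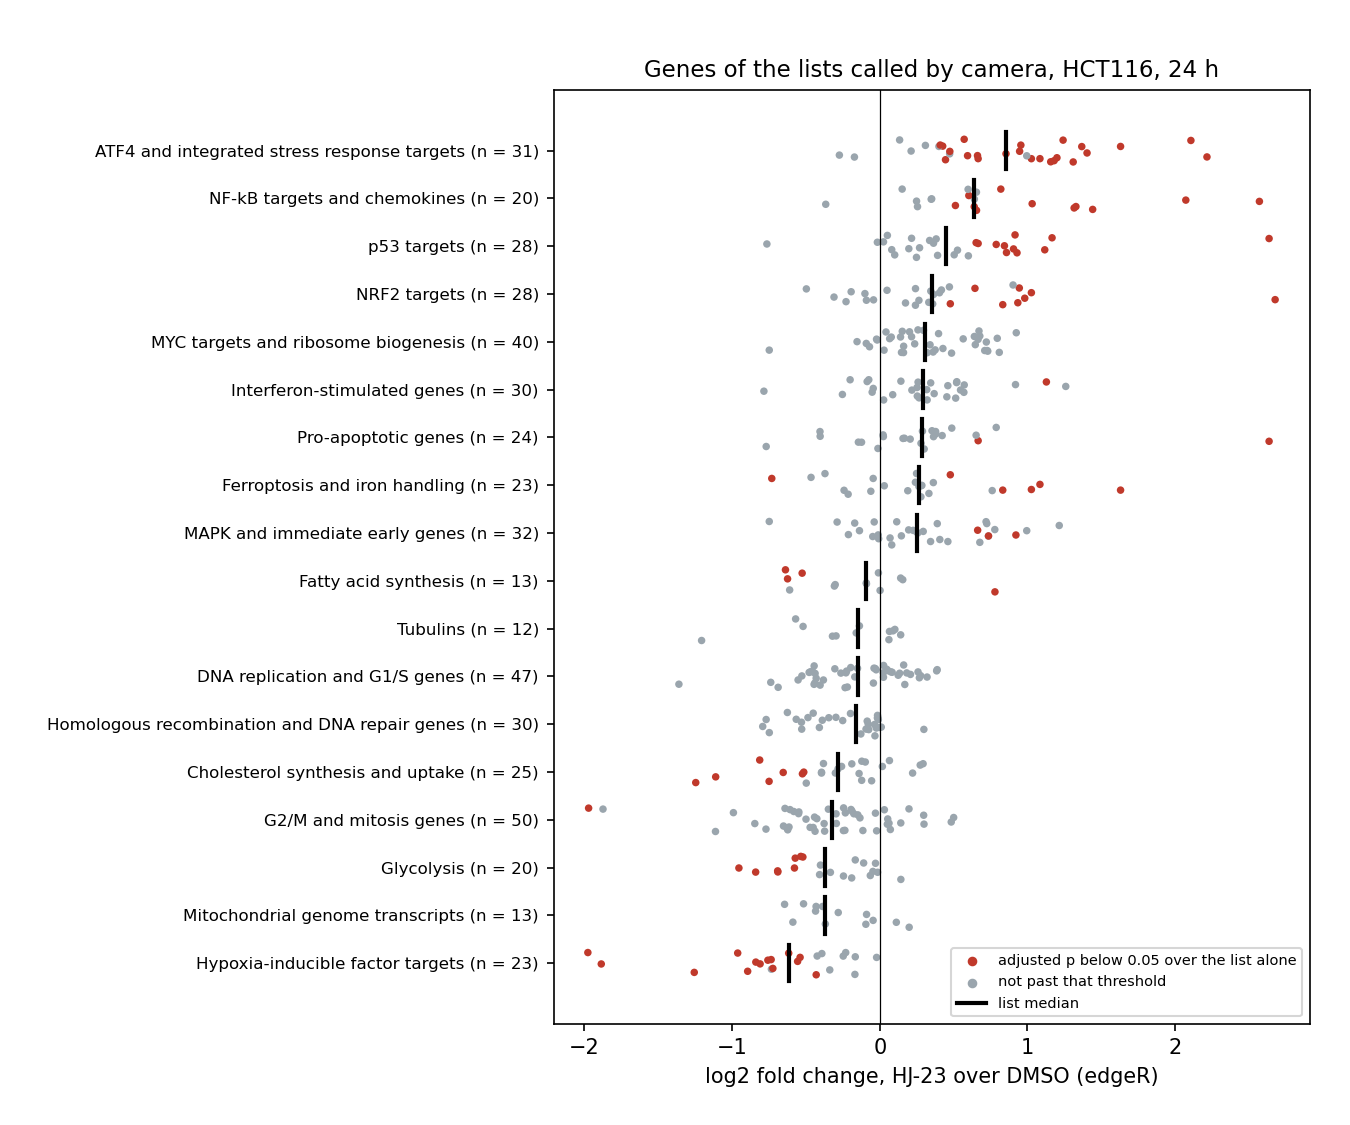
Each point is the log2 fold change (HJ-23 over DMSO, edgeR) of 1 gene of the 18 lists called by camera, red where it passed when adjusted over the list alone, and the black bar is the list median. Medians run from 0.85 for the ATF4 and integrated stress response list to -0.62 for the hypoxia list, where all 23 members lie below 0.

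Targets of p53, the tumour suppressor transcription factor, were higher, with a median log2 fold change of 0.45 over 28 members, 26 of them positive. Of these, 11 rose and 0 fell adjusted over the list alone; over all genes tested 1 rose, BBC3. The camera adjusted p was 6.14e-13 (adjusted p = 0.194 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, fixed in advance, was at 260.1 ± 41.8 CPM in DMSO and 564.2 ± 135 in HJ-23 (log2 fold change 1.12, SE 0.22); it passed adjusted over the list alone (edgeR adjusted p = 0.0174) and not over all genes (adjusted p = 0.218, edgeR), where it passed with DESeq2. The nuclease AEN and the death receptor TNFRSF10B, chosen after their values were seen, rose adjusted over the list alone, with log2 fold changes of 1.17 and 0.67. Pro-apoptotic genes had a median of 0.28 over 24 members, with 2 rising adjusted over the list alone, BBC3 and TNFRSF10B, and 1 over all genes, BBC3 (camera adjusted p = 0.00168; adjusted p = 0.428 with an estimated correlation). Without HJ-23 replicate 2 that median was 0.14. BBC3 and TNFRSF10B are also on the p53 list, so the pro-apoptotic and p53 lists are not separate evidence. Anti-apoptotic genes were not called (adjusted p = 0.616): the median of 10 members was 0.087, while the mean and the test pointed down. Adjusted over that list alone, BIRC2 and BIRC6 fell, with log2 fold changes of -0.90 and -1.08.

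Targets of NF-kB, including the neutrophil-attracting chemokines, were higher, with 19 of 20 members positive and a median log2 fold change of 0.64. Adjusted over the list alone 11 rose, and 0 passed over all genes (camera adjusted p = 9.68e-15; adjusted p = 0.194 with an estimated correlation). CXCL8 was at 10.6 ± 1.03 CPM in DMSO and 26.7 ± 3.30 in HJ-23, CXCL1 at 5.23 ± 1.16 and 14.2 ± 0.34, and CXCL3 at 1.07 ± 0.40 and 6.39 ± 0.22. These chemokines, chosen after their values were seen, rose adjusted over the list alone (edgeR adjusted p = 0.00272, 0.00316 and 0.00262). Reads of CXCL1, CXCL2 and CXCL3, which are close in sequence, may be shared in the authors' counting. Interferon-stimulated genes had a median of 0.29 over 30 members, of which 1 rose adjusted over the list alone, the transcription factor IRF1 (log2 fold change 1.13, SE 0.15), and 0 over all genes (camera adjusted p = 5.55e-04; adjusted p = 0.282 with an estimated correlation). Genes of MAPK signalling and the immediate early response had a median of 0.25 over 32 members, 3 rising adjusted over the list alone, JUNB, IER3 and EGR2, and 0 over all genes (camera adjusted p = 1.69e-04; adjusted p = 0.476 with an estimated correlation). That median was 0.41 without HJ-23 replicate 1 and 0.13 without HJ-23 replicate 2.

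Targets of NRF2, the regulator of the antioxidant response, were higher, with a median log2 fold change of 0.35 over 28 members. There were 8 that rose adjusted over the list alone and 0 that passed over all genes (camera adjusted p = 1.83e-08; adjusted p = 0.194 with an estimated correlation). Sulfiredoxin SRXN1 was at 212.1 ± 3.93 CPM in DMSO and 408.3 ± 23.1 in HJ-23, and thioredoxin reductase TXNRD1 at 354.9 ± 12.1 and 678.5 ± 20.7. SLC7A11, the cystine importer, was at 113.4 ± 3.37 and 230.9 ± 53.4 CPM. SRXN1, TXNRD1 and SLC7A11 were chosen after their values were seen, and rose adjusted over the list alone. HMOX1, heme oxygenase 1, fixed in advance, was at 21.6 ± 1.31 and 38.5 ± 5.20 CPM (log2 fold change 0.83, SE 0.18, adjusted p = 0.233, edgeR), and passed over all genes with DESeq2. Ferroptosis and iron handling genes had a median of 0.27 over 23 members, with 5 rising and 1 falling adjusted over the list alone and 0 passing over all genes (camera adjusted p = 0.0167; adjusted p = 0.405 with an estimated correlation). Those that rose included SLC7A11, HMOX1, SLC3A2 and CHAC1. SLC7A11 is also on the NRF2 list, so the ferroptosis and NRF2 lists are not separate evidence. The member of the ferroptosis list that fell was SAT1, a polyamine acetyltransferase (log2 fold change -0.73, SE 0.13). Without DMSO replicate 2 this list was not called (adjusted p = 0.0602), and its median was 0.11 without HJ-23 replicate 2 and 0.15 with the GC and length correction.

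All 23 tested targets of the hypoxia-inducible factors had negative log2 fold changes, with a median of -0.62. Adjusted over the list alone 14 fell; over all genes 1 fell, BNIP3L (camera adjusted p = 7.20e-20; adjusted p = 0.194 with an estimated correlation). ANKRD37 was at 58.8 ± 13.3 CPM in DMSO and 15.9 ± 2.12 in HJ-23, the glucose transporter SLC2A3 at 350.6 ± 4.62 and 207.3 ± 19.8, and BNIP3, the relative of BNIP3L, at 181.3 ± 8.40 and 97.54 ± 16.1. All 3 were chosen after their values were seen and fell adjusted over the list alone. Glycolysis genes were lower, 19 of 20 negative, with a median of -0.37; 8 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 9.85e-09; adjusted p = 0.428 with an estimated correlation). Among them PGK1 was at 1420 ± 60.0 and 793.0 ± 26.1 CPM and the aldolase ALDOC at 463.3 ± 36.9 and 239.2 ± 8.05, both chosen after their values were seen. GAPDH, fixed in advance, had a log2 fold change of -0.52 (SE 0.16, adjusted p = 0.325, edgeR), and ACTB, the other common reference gene, one of 0.63 (SE 0.19, adjusted p = 0.331, edgeR); neither passed.

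Genes of cholesterol synthesis and uptake were lower, with a median log2 fold change of -0.28 and 20 of 25 members negative. Adjusted over the list alone 7 fell, and 0 passed over all genes (camera adjusted p = 4.22e-07; adjusted p = 0.428 with an estimated correlation). INSIG1, the sterol-regulated brake on SREBP processing, was at 547.4 ± 35.9 CPM in DMSO and 253.4 ± 25.4 in HJ-23, and IDI1, an isoprenoid enzyme, at 293.7 ± 14.02 and 167.2 ± 7.21. Both were chosen after their values were seen. Without HJ-23 replicate 2 the list's median was -0.46. Fatty acid synthesis genes had a median of -0.091 over 13 members, with SCD, ACACA and LPIN1 falling and FADS2 rising adjusted over the list alone and 0 passing over all genes (camera adjusted p = 0.0430; adjusted p = 0.428 with an estimated correlation). That call was lost without DMSO replicate 1 (adjusted p = 0.216), DMSO replicate 2 (0.0653) or HJ-23 replicate 1 (0.296), and the median was -0.060 without DMSO replicate 1, -0.189 without DMSO replicate 2, -0.31 without HJ-23 replicate 2, -0.196 with no filter and -0.22 with the GC and length correction.

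Genes of G2/M and mitosis were lower, 39 of 50 negative, with a median log2 fold change of -0.32 (camera adjusted p = 3.40e-06; adjusted p = 0.476 with an estimated correlation). Summed over the list, the levels were 4293 and 5157 CPM in DMSO replicates 1 and 2 and 4302 and 3744 in HJ-23 replicates 1 and 2, so the replicate 1 libraries of the groups were alike. The median was -0.19 without DMSO replicate 2, -0.18 without HJ-23 replicate 2, -0.51 without DMSO replicate 1 and -0.56 without HJ-23 replicate 1, with the call held each time. MKI67, the proliferation marker fixed in advance, was at 213.7 ± 56.5 CPM in DMSO and 54.5 ± 5.61 in HJ-23 (log2 fold change -1.97, SE 0.22); it was the only member to pass adjusted over the list alone (edgeR adjusted p = 0.00549), and 0 passed over all genes (MKI67 adjusted p = 0.0735, edgeR); with DESeq2 and with the GC and length correction MKI67 passed over all genes. PLK1 and CDC25B, mitotic regulators, had positive log2 fold changes of 0.50 and 0.48 and did not pass. DNA replication and G1/S genes had a median of -0.15 over 47 members and homologous recombination and DNA repair genes one of -0.16 over 30, with 0 members passing adjusted over either list alone or over all genes. Their camera adjusted p-values were 0.0302 and 0.00273 (adjusted p = 0.417 and 0.592 with an estimated correlation). The replication call was lost without DMSO replicate 1 (adjusted p = 0.0731), DMSO replicate 2 (0.0800) or HJ-23 replicate 1 (0.244), and the repair call without DMSO replicate 2 (0.121) or HJ-23 replicate 2 (0.313). The replication median was -0.087 without HJ-23 replicate 1 and -0.049 with a filter at 10 CPM. The repair list summed to 694.2 and 815.1 CPM in DMSO and 698.8 and 602.9 in HJ-23, with a median of -0.101 without DMSO replicate 2, -0.30 without DMSO replicate 1 and -0.54 without HJ-23 replicate 1. Tubulins had a median of -0.15 over 12 members with 0 passing (camera adjusted p = 0.0404; adjusted p = 0.663 with an estimated correlation), and the call was lost without DMSO replicate 1 (0.175) or HJ-23 replicate 1 (0.669), and the median was 0.0043 without HJ-23 replicate 1 and -0.35 without HJ-23 replicate 2 or with the GC and length correction.

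MYC targets and ribosome biogenesis genes were higher, 34 of 40 positive, with a median log2 fold change of 0.31 and 0 members passing adjusted over the list alone or over all genes (camera adjusted p = 3.25e-06; adjusted p = 0.405 with an estimated correlation). The median was 0.21 without HJ-23 replicate 1. MYC itself, fixed in advance, was at 15.7 ± 2.83 CPM in DMSO and 9.32 ± 4.72 in HJ-23 and did not pass (log2 fold change -0.75, SE 0.37, adjusted p = 0.469, edgeR). Transcripts of the mitochondrial genome had a median of -0.37 over 13 members with 0 passing (camera adjusted p = 0.00256; adjusted p = 0.592 with an estimated correlation). They held 6.59% and 7.73% of counts in the DMSO libraries and 6.41% and 5.12% in the HJ-23 libraries. That call was lost without DMSO replicate 2 (adjusted p = 0.0971, median -0.23), without HJ-23 replicate 2 (0.127) or after a correction for transcript GC content and length (0.0635).

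The other tested lists were not called. Their medians (camera adjusted p) were -0.12 for heat shock factor targets (0.0760), 0.27 for replication-dependent histones (0.105), 0.23 for mesenchymal transition genes (0.101), 0.23 for enterocyte, goblet and differentiation markers (0.100), -0.069 for cytosolic ribosomal proteins (0.156) and 0.19 for YAP and TEAD targets (0.168). They were -0.064 for nuclear-encoded oxidative phosphorylation (0.279), 0.047 for autophagy and lysosome genes (0.327), 0.13 for epithelial junction genes (0.454), -0.086 for WNT and beta-catenin targets (0.498), -0.048 for xenobiotic metabolism and efflux (0.838) and 0.017 for proteasome subunits (0.838). For aryl hydrocarbon receptor targets the median was -0.097 while the test pointed up (0.838). Metallothioneins and the fibroblast, leukocyte, endothelial and erythroid markers had 4 tested members each, too few for the test, with medians of 0.028, 0.29, 0.17, 0.23 and -0.19 and 0 members passing.

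Libraries differed along transcript GC content within each group. Across the 14047 genes with a GC value, HJ-23 replicate 1 minus replicate 2 had a Spearman correlation with GC content of -0.63 and DMSO replicate 1 minus replicate 2 one of 0.35; genes are not independent replicates. The mean difference of HJ-23 from DMSO had one of 0.38. The SD of log2 differences between libraries was 0.504 for the DMSO pair and 0.531 for the HJ-23 pair. Across groups, HJ-23 replicate 1 was at 0.519 and 0.529 from DMSO replicates 1 and 2, slightly less than from its own replicate, and HJ-23 replicate 2 at 0.584 and 0.670. With each library corrected for GC content and length, an alternative added after seeing the data, 21 genes were higher and 13 lower, including the 12 called without it, and 17 of the 18 list calls held.

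**Figure D3:**
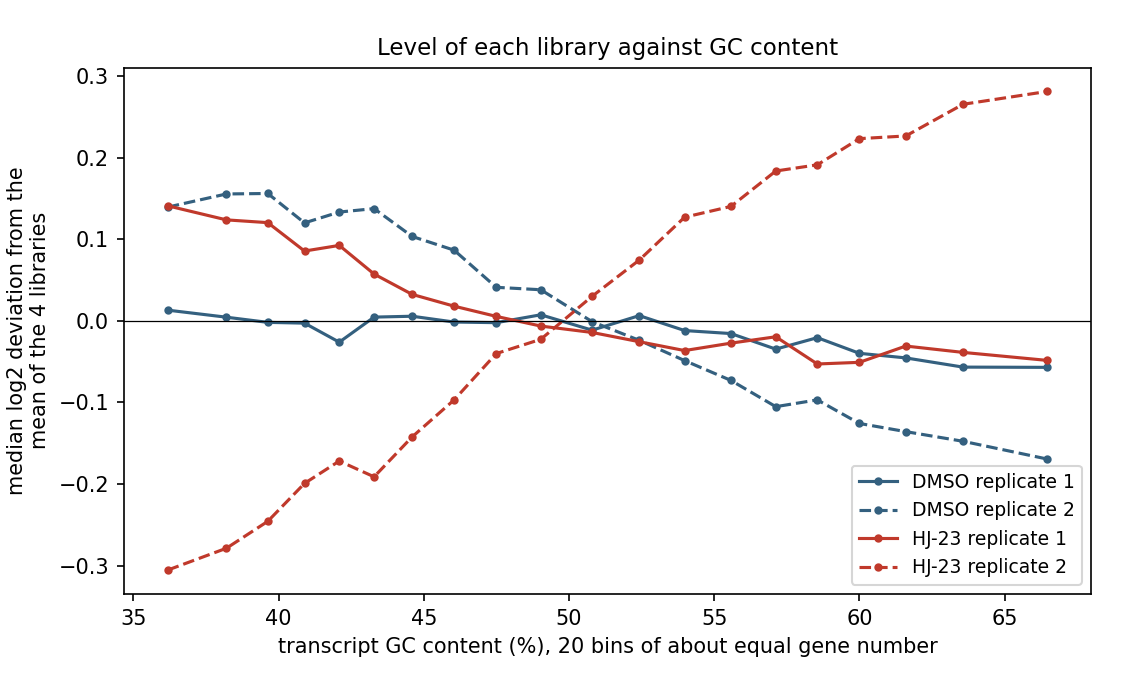
Median log2 deviation of each library from the mean of the 4 libraries, in 20 bins of transcript GC content (%), with blue lines for DMSO, red for HJ-23, solid for replicate 1 and dashed for replicate 2. HJ-23 replicate 2 rises with GC content and DMSO replicate 2 falls, and the difference between the 2 HJ-23 libraries has a Spearman correlation with GC content of -0.63.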

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

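The corrections for GC content, alone or with length, every fit that includes one, the crossed block and the fit without readthrough genes were chosen after seeing the data; the other alternatives were fixed before. The 12 called genes were also called by every alternative that tested them, except no TMM scaling (11), the filter at 10 CPM (0 of the 9 it tested), the fits without an HJ-23 library (0) and the replicate block with the GC and length correction (0). Counts of genes, higher and lower, were 8 and 4; with no filter they were 18 and 13, all at least 2-fold, over 16717 genes, and with the filter at 10 CPM 0 and 0 over 10094 genes (0 and 0 at least 2-fold; 1253 at an unadjusted p below 0.05, edgeR). DESeq2 called 161 and 150, 75 and 67 of them at least 2-fold. GC correction gave 21 and 11 (19 and 11 at least 2-fold), GC and length correction 21 and 13 (19 and 13), and leaving out readthrough genes 5 and 3 (5 and 3), since 4 of the 12 are such genes. Leaving out 1 library gave 0 to 112 higher (0 to 112 at least 2-fold) and 0 to 161 lower (0 to 160): 273 in all without DMSO replicate 1, 157 without DMSO replicate 2 and 0 without either HJ-23 library (edgeR; 3501 and 1377 at an unadjusted p below 0.05), where the lone library is assumed to vary like the other group. The cause was not tested.

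With the replicate block the counts were 136 and 158 (110 and 115 at least 2-fold), and with the block and the GC and length correction 0 and 0 (0 and 0; 1588 at an unadjusted p below 0.05, edgeR). No shared effect of the replicate number was seen: the correlation of the libraries' deviations was -0.18, and -0.093 after the correction. Only 2 libraries per group enter it, and before the correction their differences ran along GC content in opposite directions (Spearman 0.35 in DMSO, -0.63 in HJ-23). It therefore cannot show whether the libraries were paired. A crossed block, DMSO replicate 1 with HJ-23 replicate 2, gave 454 and 512 (95 and 89 at least 2-fold), and 112 and 102 (41 and 32) with the correction. Each block leaves 1 residual degree of freedom.

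The list counts of 9 and 9 became 0 and 0 with an estimated correlation, with or without the GC and length correction, where smallest adjusted p-values were 0.194 and 0.174, and 3 and 1 with fry. Leaving out 1 library gave 8 to 11 higher lists and 5 to 9 lower. The lists that lost their call were the fatty acid, replication, tubulin, repair, mitochondrial and ferroptosis lists. The median of the tubulin list without HJ-23 replicate 1 was 0.0043, though the test still pointed down. The block lost only the fatty acid list and, with the correction, only the mitochondrial list. Some lists were gained: heat shock factor targets and ribosomal proteins with GC correction, alone or with length, heat shock factor targets with the block and correction, and those 2 and YAP and TEAD targets with the crossed block and correction. Leaving out a library gained histones (DMSO replicate 1 or HJ-23 replicate 1), mesenchymal genes (HJ-23 replicate 1) or ribosomal proteins and oxidative phosphorylation (HJ-23 replicate 2). Lists whose test changed direction under a setting were called neither in the full data nor under that setting. The anti-apoptotic list had medians of 0.074 with the block, 0.11 with GC correction, 0.146 with GC and length correction (0.146 with an estimated correlation too), and 0.148 with that correction and either block. Leaving out 1 library moved its median from -0.050 to 0.13, that of the unfolded protein response list from -0.016 to 0.093, that of the aryl hydrocarbon receptor list from -0.13 to 0.19, that of the ribosomal protein list from -0.19 to 0.043, that of the oxidative phosphorylation list from -0.21 to 0.064 and that of the proteasome list from -0.058 to 0.061. No setting varied the depth. At these depths edgeR recovered 43.0% of simulated changes of 1 on the log2 scale without a library trend. It recovered 40.4% with the libraries' own trend within each group. The simulations without a trend gave 157.8 calls on average, against 12 in the real data, so these rates do not carry over to the real data. The smallest absolute change among the 12 called genes was that of GNA12, at -1.82.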

Other observations

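The GC and length test, the readthrough tests and the test of response strength were chosen only after the results were seen, as were the lists in the next paragraph; the test of exchanged labels was fixed before. The next gene groups were looked at in addition. Type III interferons and secreted cytokines had a median log2 fold change of 1.14 over 9 tested members, 8 of them positive. Since these groups were put together from the values, no test of them is given; 0 of their members passed over all genes (edgeR). IFNL1 was at 4.84 ± 0.61 CPM in DMSO and 13.3 ± 2.00 in HJ-23 (mean ± SD, n = 2), IFNL2 at 7.11 ± 0.24 and 17.2 ± 1.66, and IFNL3 at 7.93 ± 1.11 and 20.9 ± 0.16; IFNL2 and IFNL3 are near-identical, so reads assigned to each are uncertain. CSF2, the growth factor GM-CSF, was at 0.96 ± 0.05 and 3.47 ± 0.96.

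Circadian clock genes had a median of 0.34 over 17 members, 11 of them positive. The nuclear receptor NR1D1 was at 196.1 ± 17.4 and 532.8 ± 88.2 CPM and the activator DBP at 97.9 ± 14.6 and 202.2 ± 33.8, while the repressor CRY2 was at 56.9 ± 8.48 and 32.5 ± 3.50. Cytosolic aminoacyl-tRNA synthetases had a median of 0.26 over 20 members, 15 of them positive; AARS1 was at 349.7 ± 10.1 and 674.1 ± 76.6 and MARS1 at 120.0 ± 4.12 and 202.4 ± 11.9. Among genes that edgeR called with the GC and length correction and not without it, and that DESeq2 called too, the cadherin FAT1 was at 592.7 ± 99.1 and 178.8 ± 19.8 CPM and ARRDC4, an arrestin-domain gene responsive to glucose, at 378.7 ± 12.4 and 112.7 ± 36.2.

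Replicate libraries differed along transcript GC content. The trend between the groups was small beside the changes of the called genes. It was not small beside the medians of some called lists, such as -0.15 for the replication list and 0.27 for the ferroptosis list. The median log2 difference, HJ-23 minus DMSO, was -0.16 in the 10% of genes with lowest GC and 0.22 in the highest 10%. By length it was 0.059 in the shortest 10% and -0.21 in the longest 10%. The smallest absolute change among the 12 called genes was -1.82, so this trend as their whole origin is argued against. All 12 were also called after the correction. Removing so small a trend could hardly undo changes of that size, so this count is no separate test. The corrected fit called 34 genes against 12, with the biological coefficient of variation at 16.4% against 19.6%. It is what a trend that widened the spread and lowered the count of calls would give. Subtracting a fitted trend already seen to differ within the groups lowers the spread by itself, so these values are no separate test either. A stronger response in HJ-23 replicate 2 stays open. After the correction the integrated stress response list was higher there by a median of 0.14, at percentile 99.4 of 10000 random lists matched on level. Its genes move together (estimated correlation 0.14 without the correction), so that this percentile is too extreme. The hypoxia list, with an estimated correlation of -0.027, was at a median of -0.010, percentile 20.8.

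Readthrough genes made up 4 of the 12 calls, 1.45% of the 276 tested against 0.0580% of the 13786 other genes. A Fisher's exact test of these counts (two-sided, p = 6.35e-05) was run after they were noticed among the calls, so it restates that observation and is no independent evidence. A different assignment of shared reads in the 2 groups would move the overlapping genes the other way. They did so for 4 of 4, but by more than the sum of their SDs for only 2: SRCAP and TMEM265 fell by 25.4 CPM together as ENSG00000282034 rose by 32.1, and BBS1 and DPP3 rose by 12.2 as ENSG00000256349 fell by 6.87. The locus totals changed by at most 0.16 on the log2 scale, which a switch between transcripts of the same locus would give too. At each locus the overlapping genes together were at higher levels than the readthrough gene. For ENSG00000282034 the HJ-23 means were 85.3 against 36.8 CPM. A total could therefore change only modestly whatever the cause, and its small change favours no explanation. The 2 explanations, and others that were not tested, cannot be told apart from gene counts, which do not show which exons the reads cover.

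An exchange of the group labels was tested because the deposited tables carry the letter C for the libraries titled HJ-23, and the treatment field and the titles name the compound differently. If the libraries labelled HJ-23 were the controls, the integrated stress response list would be lower there and the G2/M list higher, on the assumption that the compound inhibits growth. The medians were 0.85 and -0.32, both past the camera threshold at the preset correlation, which argues against it under that assumption. With an estimated correlation neither list passed (adjusted p = 0.194 and 0.476), and the summed G2/M levels of the replicate 1 libraries were alike (4293 CPM in DMSO, 4302 in HJ-23), so the argument is weak and rests mainly on the integrated stress response list.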
